A study of Zea mays with 153 samples.

How the data were processed

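The series measured gene expression in leaf tissue of maize (Zea mays) plants grown for 45 days in a greenhouse, per the labels' protocols. A disomic haploid carries a single copy of the genome plus an extra dose of a chromosome arm, which was added through a translocation between that arm and the supernumerary B chromosome. There were 153 samples in all. Of these, 113 were RNA libraries made after removal of ribosomal RNA, 37 were RNA libraries made by poly(A) selection and 3 were DNA libraries. Groups and replicate numbers were taken from the sample titles. The labels named a plant for each library, so the replicates of a group were separate plants, while the poly(A) libraries came from plants that also had an rRNA-depleted library.

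Per the submitters' processing notes, cutadapt, Bowtie2, TopHat2 and Cuffdiff were used, with no versions or roles given. The genome build and the annotation were not given in the sources used here, and coordinates are printed as the authors' tables list them, counted from 1. The deposited FPKM values per sample (fragments per kilobase of gene, scaled to library size) were given in a separate table for each comparison. The authors' comparison tables held a mean FPKM for each group, a p-value and a q-value per gene, per the file headers, which have the layout of Cuffdiff output. For DNA, the deposited signal was given in bins of 1 Mb, scaled to the same sum in each library, with deposited RPKM values per gene (reads per kilobase, scaled to library size). The authors' ratio of each disomic library to the haploid library was not used, and the ratio printed here was computed from the signal and divided by its median over the other 9 chromosomes. In 18 of the 19 comparisons the mean of the per-sample FPKM values equalled the authors' deposited group mean to within 0.1% (of a mean of at least 0.01 FPKM) at 100% of genes. In the 3La comparison it held at only 30.1% of genes for the disomic group. The per-sample values there included 1 column whose name belongs to another disomy, and this column was not used, so the authors' deposited 3La values may rest on other samples than the 3 used here. The labels list 1 more 3La disomic plant, which has no column of its own. Whether the unused column stands for it could not be told. In all, 112 rRNA-depleted libraries were in use. The design was written on the assumption that tables were normalised separately. Of the 38 control columns that appeared in more than 1 table, however, only 2 values differed, so a control library had the same FPKM in every table.

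For each of 19 comparisons (17 disomies and the plants with 1 or 2 B chromosomes) genes were tested with limma 3.58.1 in R 4.3.3 (files were read with version 1.17.8 of data.table), on log2(FPKM + 1). Genes with a mean FPKM of at least 1 over the samples of the comparison entered the fit, and the spread was moderated with a trend on mean expression. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Genes were divided into the tip of the varied arm (genes within 30 Mb of that end of the chromosome, taken as the end of its last gene for long arms), the rest of that chromosome and the other 9 chromosomes, called trans here. For the 2Sa and 2Sa deletion disomies the tip was replaced by the longest run of DNA bins with a ratio to the haploid of at least 1.5. An arm score was computed for each sample as the median over tip genes of the log2 value minus the mean of both group means, after subtracting the same median over trans genes. Scores were compared by an exact permutation test, one-sided for higher scores in the disomics, and p-values were adjusted over the 17 disomies by Benjamini-Hochberg. The edge of the region with raised expression was estimated as the single change point along the chromosome that left the least squared deviation, with at least 10 genes on each side, and its range covers 95% of 200 bootstrap draws of genes. Bins of DNA were split into segments of at least 4 bins by binary segmentation.

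The tests of the comparisons, the arm scores, the filter, the pseudocount, the alternatives and the rule for naming genes were fixed before the data were examined. Chosen later were the DNA segments, the fits between haploid sets, the limit of 7 of 8 control sets, the grouping of plastid genes, the count without the 5Sc set and the fits of same-numbered samples without a block. The naming rule asked for genes with a symbol or a described product, and for those called in most control sets, ranked by number of sets and then by mean change. However, 0 of the 40270 nuclear gene IDs matched any of the 49888 genes of the reference table, whose assembly was Zm-B73-REFERENCE-NAM-5.0. The 15 gene lists and 5 cell type lists that had been planned were therefore void, and their tests were not run, with the exception of the organelle genes, which the authors' tables name. The first 2 IDs that rose and the first 2 that fell in that ranking are printed, and other genes are given by position. For the ranking a call counted only where every disomic plant lay beyond every control plant.

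Correlations of fold changes between disomies were computed across genes outside both varied chromosomes, and genes are not independent replicates, so no p-value was attached to them. For disomies with the same haploid control, unchanged groups were simulated against those controls in 50 draws, and the controls were divided where each part kept at least 2 libraries. Genes called in most control sets were counted so that a control set counted only once, and chance values came from 200 shuffles of the calls over genes.

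The files hold no read counts. The sum of FPKM per library ranged from 641511 to 836099, and from 17400 to 20475 genes reached an FPKM of at least 1. Relative depth was estimated from the steps between low values below 0.3 FPKM and ranged from 0.141 to 1 over the 112 libraries, with a median of 0.588. The estimate was rough, since at most 29.7% of low genes lay at the most frequent step. The ratio of depth between disomic and control libraries ranged from 0.770 to 2.46. The correlation of 2 samples of 1 group ranged from 0.871 to 0.985, across genes.

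Replicate numbers recur between groups in the labels, and whether they pair plants was checked by the correlation of the deviations of same-numbered samples from their group means. In 1 of the 19 comparisons, 4Lb, every pair correlated above 0.1, from 0.103 to 0.129, so its numbers were treated as pairing the samples by this check of the data and not by any statement in the labels. The same control plants had the same numbers in 3Sb, where pairs correlated from -0.259 to 0.0318, so a true pairing was not shown. The calculations were tested on simulated data with 200 changed genes. In the 8Lc comparison, with 20251 genes tested, 58% of genes changed by a log2 value of 1 and 90% of those changed by 2 were recovered. With the 3 against 3 samples of 6Lc, over 19534 genes, these shares were 41% and 81%, with the 5 against 5 samples of 10L19, over 19203 genes, 88% and 99%, and with the 4 against 3 samples of the 2 B comparison, over 19389 genes, 40% and 78%. A simulated change point in the 8Lc data was found within 0.103 Mb.

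The alternatives were a pseudocount of 0.1, no filter on low values, centring each sample on its median trans gene, the authors' deposited Cuffdiff q-values, the replicate number as a block, and leaving out each sample in turn. For the arms a tip of 15 Mb, a least mean FPKM of 5 and the region from the estimated change point were also tried.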

Results

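The study set plants with 2 doses of a chromosome arm against haploid plants with 1 dose, in 17 disomies that covered arms of all 10 chromosomes. Expression was measured in leaves by RNA sequencing after removal of ribosomal RNA, with 3 to 6 disomic and 3 to 5 haploid plants per comparison. The 17 disomies were set against 8 haploid control sets, of which 6 served more than 1 disomy. In 6 disomies the comparison was also made with poly(A)-selected libraries, and for the 2Sa and 2Sa deletion disomies genomic DNA was sequenced from 1 plant each, beside 1 haploid plant. By its label this haploid plant was not among the RNA controls of these disomies, so their DNA and RNA ratios rest on different haploids. Haploids with 1 or 2 B chromosomes were compared with haploids that had none. All values are FPKM as deposited, and depth is known only in relative terms, from 0.141 to 1 over the libraries.

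The first question was how far the expression of genes on the varied arm followed its dose. Genes at the tip of the arm were expressed at a higher level in the disomics in all 17 disomies, by a fold of 1.68 in 3Sb to 1.89 in 4Lb, with a median of 1.82, and the arm score of every disomic plant lay above that of every haploid control. The log2 difference of the arm scores ranged from 0.75 to 0.92, and its SE from 0.0076 to 0.0294. These folds rest on log2(FPKM + 1) and on subtracting the median over trans genes. The ratio of group means, not so centred, had a median over tip genes from 1.599 in 1Sb to 2.085 in 4Sa. Its median over the 17 disomies was 1.886. How closely the response came to a ratio of 2 therefore depends on the measure. For 2Sa, also at a fold of 1.89, and for the 2Sa deletion the region scored was a run of bins chosen by DNA ratio instead of a tip of 30 Mb. The log2 difference of 2Sa was 0.92 over that run, 0.79 over a tip of 15 Mb and 0.84 over the region from the estimated change point. Single genes varied widely around these values. From 32.7% to 54.5% of the tip genes of a disomy had a ratio of group means from 1.6 to 2.5, from 8.01% to 17.8% had a ratio between 0.8 and its reciprocal, and from 3.26% to 11.9% lay below 0.8. Between 41.4% of tip genes (1Sb) and 79.4% (10L19) were called higher, and between 0.339% (7Sc) and 5.55% (9Lc) were called lower. By the exact permutation test, 15 of the 17 arms passed an adjusted p of 0.05. The remaining 2, 3La and 6Lc, had 3 plants per group, where the smallest p the exact test can give is 0.05, and both reached it.

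**Figure D1:**
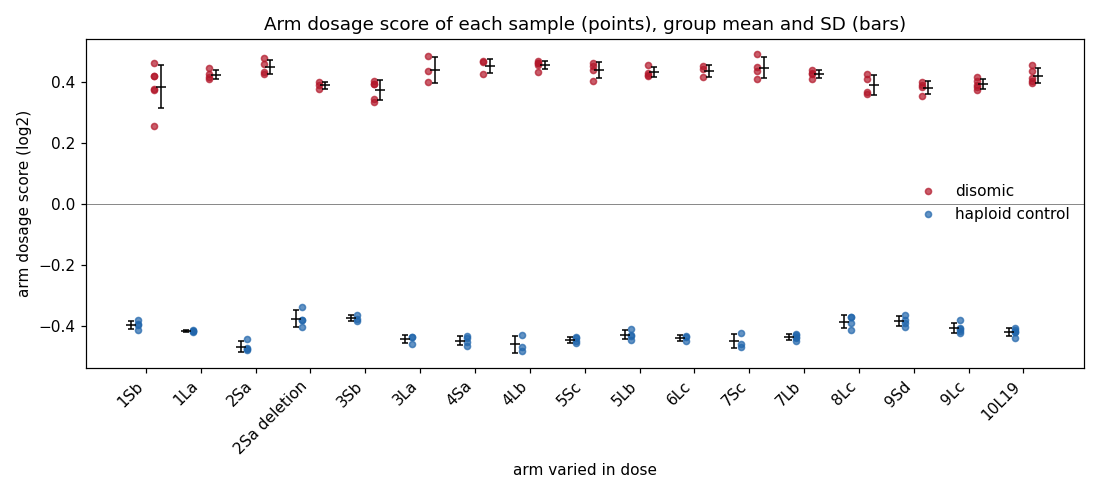
Arm dosage score of each sample (points, log2 scale) in the 17 disomies, with the mean and SD of each group (bars). The disomic samples (red) lie above 0 and the haploid controls (blue) below 0 in all 17, and the lowest disomic score is 0.26 in 1Sb.

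Along the varied chromosome, raised expression ended at a position that was estimated from RNA alone. Inside the region the median gene was higher by a log2 value of 0.74 to 0.93 in every disomy except the 2Sa deletion, where the single change point left segments of several doses on the same side and the median was 0.20. On the rest of the chromosome the median log2 difference lay between -0.054 and 0.053. The edge was placed on these same expression values.

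For chromosome 1, the 1Sb disomy (6 disomic and 4 haploid plants) raised its tip genes by 0.78 ± 0.029 on the log2 scale (SE, exact p = 0.00476), and the raised region ran from the end of the short arm to 129.77 Mb, with a range of 123.83 to 130.33 Mb. Among 15957 genes of the other chromosomes 495 were called higher and 2094 lower, and the median of these genes lay at -0.24. After centring on the median trans gene, 994 were higher and 1149 lower, so the share of lower calls moved from 80.9% to 53.6%. The 100 genes with the most FPKM took 34.1% of the total in the disomics and 26.1% in the controls, and disomic replicate 3, at 25.4%, stood apart from the other disomics at 32.4% to 41.4%. Without that plant 6477 genes were called instead of 3420. The count was 1443, 1700, 1898 and 1880 without haploid control replicate 1, 2, 3 and 4, and 2257 without disomic replicate 1. The 1La disomy (4 against 4) raised its tip genes by 0.84 ± 0.0078 (exact p = 0.0143), and the raised region began at 161.91 Mb (157.44 to 185.26 Mb). It had 1539 higher and 3268 lower trans calls, which became 2509 and 2300 after centring.

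On chromosome 2, the run of bins from 8 to 41 Mb with a DNA ratio of at least 1.5 in the 2Sa disomy (4 disomic and 4 haploid plants) was expressed higher by 0.92 ± 0.015 (exact p = 0.0143), with 343 of its 521 genes called higher and 8 called lower. Genes on the other chromosomes gave 1901 higher and 2966 lower calls. In the 2Sa deletion disomy (3 against 4) the region from 69 to 93 Mb was higher by 0.77 ± 0.015 (exact p = 0.0286), with 61 of 102 genes called higher and 2 lower, and 753 trans genes were called higher and 1045 lower. Of its 2282 calls in all, 837, 1049 and 1111 remained as a count without disomic replicate 1, 2 and 3, and 1520 without haploid control replicate 3. The balance of its trans calls turned to 306 higher and 275 lower, 415 and 339, and 422 and 389 without disomic replicate 1, 2 and 3, and to 644 and 543 without haploid control replicate 2. After centring it was 893 and 918.

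The DNA of these plants gave a ratio to the haploid library along chromosome 2, from 1 library per genotype and therefore with no replicate check. This ratio cannot be read as a dose in every segment. In the 2Sa disomic the longest run of bins at a ratio of at least 1.5 extended from 8 to 41 Mb, with a median ratio of 1.98, and in the deletion disomic from 69 to 93 Mb, with a median of 1.99. Both plants had a ratio near 2 from 72 to 93 Mb (2.00 and 2.00) and from 106 to 122 Mb (1.97 and 2.01), and both had a ratio near 1 in the stretch between, from 93 to 106 Mb (1.05 and 1.06). From 28 to 40 Mb the ratio was 1.92 in the 2Sa disomic and 1.00 in the deletion disomic, and from 183 to 245 Mb, on the long arm, it was 0.979 and 0.978. Ratios far from both whole doses also occurred. They were 3.18 and 1.61 from 12 to 16 Mb and 2.62 and 1.36 from 21 to 28 Mb, where the signal of the haploid library itself, the denominator of both ratios, was low (medians of 0.285 and 0.320, against 0.475 on the other chromosomes). From 16 to 21 Mb, where that signal was also low (0.323), the ratios were 2.45 and 1.07. From 0 to 8 Mb the ratios were 1.51 and 0.62, from 40 to 47 Mb 1.39 and 0.495, and from 47 to 72 Mb 1.95 and 1.52. On the long arm the 2Sa disomic fell to 0.555 from 155 to 164 Mb and to 0.573 from 175 to 183 Mb, where the deletion disomic had 1.02 and 0.986. On the other chromosomes 53 of 1882 bins also reached a ratio of 1.5 in each plant.

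Expression along chromosome 2 was raised in the segments with a DNA ratio near 2 and close to the haploid level from 93 to 106 Mb. In the 2Sa disomic it was also raised from 0 to 8 Mb (fold 1.70, DNA ratio 1.51) and from 40 to 47 Mb (fold 1.77, DNA ratio 1.39). Relative to the median trans gene, the median gene from 28 to 40 Mb was expressed at a fold of 1.75 in the 2Sa disomic and 0.994 in the deletion disomic, and from 72 to 93 Mb at 1.62 and 1.75. From 12 to 16 and from 21 to 28 Mb, segments with a low haploid DNA signal, the fold was 2.13 and 2.24 in the 2Sa disomic and 1.21 and 1.18 in the deletion disomic, and 68.5% and 78.9% of genes were called higher in the former. From 16 to 21 Mb, where that signal was also low, the fold was 1.91 in the 2Sa disomic and 1.04 in the deletion disomic. From 93 to 106 Mb, where the DNA ratio was near 1, the fold was 0.938 and 1.09, and 2 and 0 genes were called higher of 34 and 35. From 106 to 122 Mb it was 1.47 and 1.61, with 33 of 73 and 37 of 74 genes called higher. On the long arm of the 2Sa disomic, from 155 to 164 and from 175 to 183 Mb, 24.6% and 27.2% of genes were called, beside 28.1% of genes on the other chromosomes, and the median gene was at a fold of 0.931 and 0.974. In plant 2S16, RNA replicate 2 and the source of the DNA by its label, the spread of genes from 155 to 183 Mb (median absolute deviation 0.612) exceeded that of its trans genes (0.530), which was not so in the other 3 plants, and its median there was the lowest of the 4, at -0.11. In the deletion disomic 19 genes were called higher and 54 lower of 219 from 0 to 8 Mb, at a DNA ratio of 0.62 and a median fold of 0.934. From 40 to 47 Mb the DNA ratio was 0.495, yet 23 of 85 genes were called higher and 13 lower, at a median fold of 1.17. From 28 to 40 Mb 7 were called higher and 9 lower of 150.

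**Figure D2:**
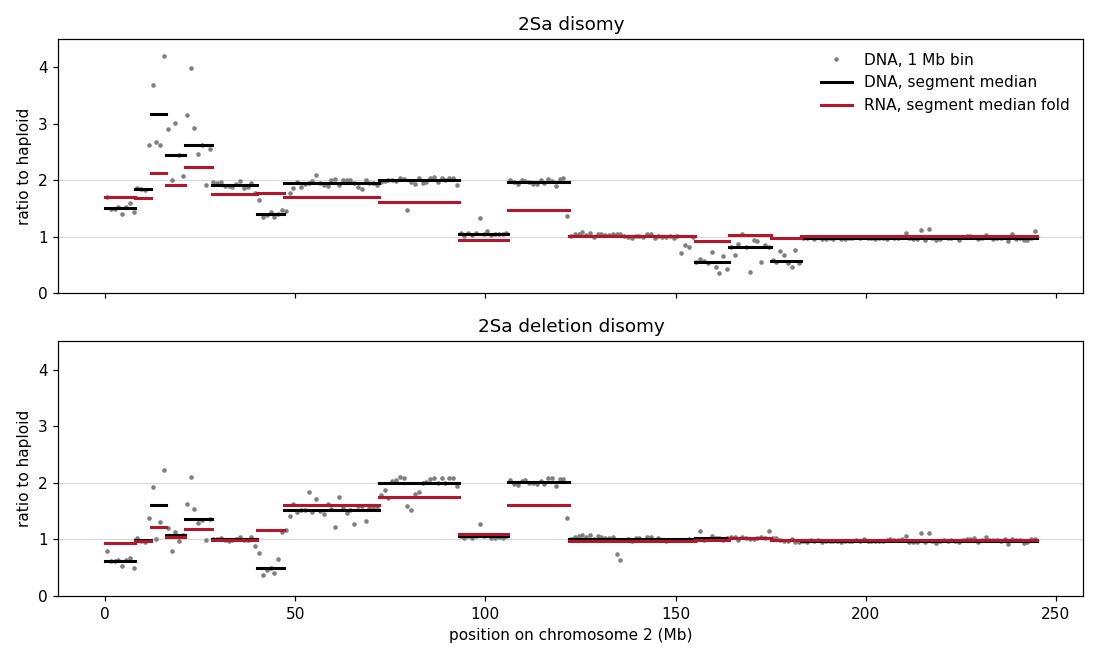
Ratio of the disomic to the haploid DNA library in 1 Mb bins of chromosome 2 (grey points) with segment medians (black), and the median RNA fold of the genes in each segment relative to the median trans gene (red), for the 2Sa disomy (top) and the 2Sa deletion disomy (bottom). Both DNA and RNA return to about 1 from 93 to 106 Mb and rise again from 106 to 122 Mb.

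The short arm of chromosome 3 was varied in the 3Sb disomy (5 disomic and 3 haploid plants), whose tip genes rose by 0.75 ± 0.015 (exact p = 0.0179), with a raised region of 38.056 Mb (33.758 to 39.325 Mb), the shortest of the 17. There were 1132 higher and 1519 lower trans calls, 57.3% lower, and 1561 and 1290, or 45.2% lower, after centring. The count of 3126 calls dropped to 1187, 1257 and 1173 without haploid control replicate 1, 2 and 3. The 3La disomy (3 against 3) had tip genes higher by 0.88 ± 0.026 (exact p = 0.05, the smallest possible) from 89.487 Mb (78.826 to 89.648 Mb) to the end of the long arm, with 1569 higher and 2129 lower trans calls. Its 4765 calls became 1904, 1396 and 1366 without haploid control replicate 1, 2 and 3, and 2796 without disomic replicate 2, and the trans calls were 474 higher and 451 lower without haploid control replicate 2.

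Both arms of chromosome 4 were expressed higher, while the number of calls on other chromosomes differed. In 4Sa (3 disomic and 4 haploid plants) tip genes rose by 0.90 ± 0.016 (exact p = 0.0286) and the raised region ended at 104.14 Mb (101.36 to 115.53 Mb). The disomy had 756 higher and 459 lower trans calls, 37.8% lower, and 631 and 580, or 47.9%, after centring. Of 1781 calls, the count was 975 and 1101 without disomic replicate 1 and 3. In 4Lb (5 against 3) tip genes rose by 0.92 ± 0.017 (exact p = 0.0179) from 170.61 Mb (169.96 to 178.19 Mb) onwards, and 2646 trans genes were called higher and 4437 lower, against 3784 and 3219 after centring. Over the 3 pairs of 4Lb the arm difference was 0.91, with an exact p of 0.125, the smallest that 3 pairs allow.

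On chromosome 5, tip genes of the 5Sc disomy (4 against 4) rose by 0.88 ± 0.014 (exact p = 0.0143) up to 83.616 Mb (83.278 to 86.223 Mb). Trans calls numbered 1495 higher and 2876 lower, 65.8% lower, and 2213 and 1863, or 45.7%, after centring. The 5Lb disomy (4 against 4) raised its tip genes by 0.86 ± 0.011 (exact p = 0.0143) from 154.19 Mb (151.73 to 162.07 Mb), with 1145 higher and 2594 lower trans calls, 69.4% lower, and 1796 and 2005, or 52.7%, after centring. Without haploid control replicate 1 its count moved from 4653 to 3096.

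The long arm of chromosome 6 in the 6Lc disomy (3 against 3) was higher at its tip by 0.88 ± 0.012 (exact p = 0.05, the smallest possible), with a raised region from 60.116 Mb (56.913 to 76.709 Mb). There were 1772 higher and 2662 lower trans calls, and 2314 and 2104 after centring. The count of 5345 became 2637, 2465 and 2448 without haploid control replicate 1, 2 and 3, and 2630 without disomic replicate 2.

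For chromosome 7, the short arm in 7Sc (4 disomic and 3 haploid plants) rose by 0.90 ± 0.022 (exact p = 0.0286) up to 53.479 Mb (52.349 to 56.444 Mb), with the fewest calls of any disomy. There were 357 higher and 340 lower trans calls, 48.8% lower, and 466 and 258, or 35.6%, after centring. The 915 calls became 379, 314 and 387 without haploid control replicate 1, 2 and 3, and 609 without disomic replicate 1, and without disomic replicate 4 the trans calls were 421 higher and 469 lower. The long arm in 7Lb (4 against 5) rose by 0.86 ± 0.0076 (exact p = 0.00794) from 86.346 Mb (86.023 to 86.512 Mb), with 3500 higher and 3658 lower trans calls. These were 3247 and 3236 without haploid control replicate 2, and 3470 and 3427 without disomic replicate 4.

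The 8Lc disomy (4 against 4) raised the tip of the long arm of chromosome 8 by 0.78 ± 0.019 (exact p = 0.0143) from 90.267 Mb (88.678 to 91.483 Mb), with 816 higher and 550 lower trans calls. On chromosome 9, the 9Sd disomy (4 against 4) raised its tip genes by 0.77 ± 0.013 (exact p = 0.0143) up to 57.507 Mb (56.765 to 59.064 Mb). It had 701 higher and 629 lower trans calls, 47.3% lower, and 646 and 889, or 57.9%, after centring. The count of 1685 was 1104 without haploid control replicate 2, and 1044, 1110 and 1104 without disomic replicate 1, 2 and 4. Without disomic replicate 3 the trans calls were 662 higher and 874 lower. The 9Lc disomy (5 against 5) raised its tip by 0.80 ± 0.010 (exact p = 0.00397) from 75.433 Mb (73.097 to 89.811 Mb), with 3934 higher and 4040 lower trans calls, which became 3823 and 3691, and 3642 and 3632, without haploid control replicate 2 and 3, and 4277 and 4220 without disomic replicate 5. The 10L19 disomy (5 against 5) raised the tip of the long arm of chromosome 10 by 0.84 ± 0.013 (exact p = 0.00397) from 51.312 Mb (29.099 to 54.573 Mb), and with 4323 higher and 5852 lower trans calls it had the most calls of the 17.

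Over the 17 disomies, the title of the series raises the question of whether genes on the unvaried chromosomes mostly moved against the dose. Between 3.92% (7Sc) and 56.4% (10L19) of trans genes were called, with a median of 21.2%. Lower calls outnumbered higher calls in 13 disomies, and higher calls were the more numerous in 4Sa, 7Sc, 8Lc and 9Sd. The median log2 change of a lower call was -0.86 at the median of the disomies, and that of a higher call 0.92. The median trans gene lay below 0 in 13 disomies, and over all 17 it ranged from -0.24 in 1Sb to 0.063 in 4Sa. Centring each sample on that gene left more lower than higher calls in 9 disomies and more higher than lower in 8. No p-value was attached to these counts, because control plants are shared between disomies.

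**Figure D3:**
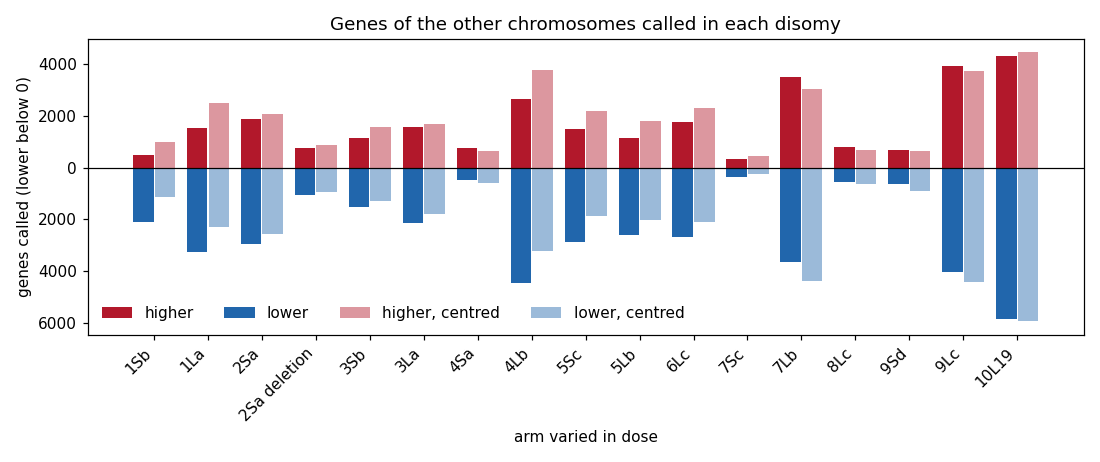
Number of genes of the other chromosomes called higher (red, above 0) and lower (blue, below 0) in each disomy, with the authors' scaling (dark) and after centring on the median trans gene (pale). Lower calls exceed higher calls in 13 disomies before centring and in 9 after it.

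Fold changes of trans genes correlated between most pairs of disomies. For the 124 pairs of disomies with separate haploid controls the correlation across genes had a median of 0.284 (-0.511 to 0.714) and was above 0 in 97. For the 12 pairs with the same haploid control the median was 0.707 (0.438 to 0.817), where groups without any effect gave 0.382 through the shared controls alone. With the controls divided between both disomies of a pair, which 8 pairs allowed, the median was 0.575. The covariance exceeded its simulated value by a median of 0.295 over the 12 pairs. In 4Lb and 6Lc, which shared controls, the correlation was 0.814 beside a simulated 0.361, and 1057 trans genes were higher and 1874 lower in both, with 23 going opposite ways. In 5Lb and 8Lc the correlation of 0.438 lay below the simulated 0.471, but the covariance of 0.170 lay above the simulated 0.0373, and the correlation was 0.327 with the controls divided. In this pair 284 genes were higher and 208 lower in both, and 21 went opposite ways. Shared controls can raise such overlaps without any common response.

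Some trans genes were called the same way in at least 1 disomy of most control sets. Of 10526 genes measured in all 8 control sets, 50 rose and 42 fell in at least 7 of the 8, where shuffled calls gave 0 and 0.56 genes. Genes of chromosomes 1, 2 and 5 could not enter this count. The 1Sb, 2Sa/2Sa deletion and 5Sc control sets served only disomies of those chromosomes. Zm00004b017856, on chromosome 3 at 157547555 to 157548603, rose in 15 of the 15 disomies in which it lay outside the varied chromosome, with a mean log2 change of 2.81. Zm00004b017804, on chromosome 3 at 155128924 to 155136505, also rose in 15 of 15, with a mean log2 change of 2.70. Zm00004b036454, on chromosome 7 at 140908885 to 140930754, was called lower with every disomic plant below every control in 10 of 15 disomies. Its mean log2 change was -0.96 (-1.85 to -0.219). Zm00004b031157, on chromosome 6 at 164106333 to 164111319, was so called in 11 of 16, with a mean of -0.84 (-1.88 to 0.118). For Zm00004b017856 the 5Sc haploid controls themselves averaged 91.5 FPKM, against 4.56 to 16.2 in the other haploid sets.

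The haploid control sets also differed from each other, although all carried 1 dose of every arm. Between pairs of the 8 sets 456 to 10810 genes were called, with a median of 5835 over the 28 pairs. This was 29.2% of the 20005 genes tested on all chromosomes, beside a median of 21.2% of trans genes called in a disomy. By the root mean square log2 difference over trans genes, only 8 of the 17 disomies lay nearest to their own control set. The haploid set of 7Lb, 9Lc and 10L19 gave 9776 to 10810 calls against each of the other 7. It was also the largest set, with 5 plants, so these counts do not rank distance alone. It gave 1846 calls against the haploids without a B chromosome, and the 1Sb set gave 10084 against the 3Sb/4Lb/6Lc set. The disomies of the 7Lb/9Lc/10L19 set had 7158, 7974 and 10175 trans calls, the most of the 17 together with 4Lb at 7083.

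Poly(A)-selected libraries of 6 disomies were compared with the rRNA-depleted ones through the authors' deposited tables of group means. In these tables the median tip gene was expressed at a ratio of 1.72 (1La), 1.79 (3Sb), 2.02 (4Sa), 1.88 (6Lc), 1.90 (7Lb) and 1.89 (9Lc) after rRNA removal and at 1.71, 1.69, 2.01, 1.85, 1.93 and 1.95 after poly(A) selection. The correlation of log2 ratios across trans genes was 0.773 in 4Sa and 0.891 to 0.919 in the other disomies. By the authors' deposited q-values, 5880 trans genes changed the same way with both kinds of library in 9Lc and 15 in opposite ways, and in 4Sa the counts were 1731 and 8. Per the labels, both kinds of library came from the same plants, so they are no independent check of the disomies.

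Haploids with B chromosomes tested for effects of the B chromosome itself, a supernumerary chromosome that maize can lack. With 2 B chromosomes (4 plants against 3 without), 2 genes were called higher and 1 lower by limma among 19389 tested, with 1122 genes at an unadjusted p under 0.05 and 433 by the authors' deposited q-values. Both higher genes are listed at chromosome 3, 233016328 to 233021824, with the same coordinates, so their values are not independent. The first was listed at 0 in all 3 plants without a B chromosome and at 6.17 to 8.69 FPKM in the 4 plants with 2 (adjusted p = 0.00329, limma). The second rose by 2.86 ± 0.20 (log2, SE, adjusted p = 0.00810, limma), from 0, 0.277 and 0.359 FPKM to 5.95 to 9.57. In the 4 plants with 1 B chromosome the first gene was at 7.70, 0, 10.6 and 5.29 FPKM and the second at 7.42, 0, 9.38 and 8.29, and both zeros belonged to replicate 2. The group means of the 17 disomies and 8 haploid control sets were at most 0.131 FPKM for these genes. The gene at chromosome 3, 10492077 to 10494924, fell by 1.54 on the log2 scale (adjusted p = 0.0377, limma), from 30.4 ± 4.57 (SD, n = 3) to 9.72 ± 0.520 FPKM (SD, n = 4), a call that ended under a pseudocount of 0.1 and after centring. The 3 genes were chosen after their values were seen. Leaving out 0 B replicate 1 or 2, or 2 B replicate 1, 2, 3 or 4, ended the call of the fallen gene (adjusted p = 0.137, 0.0619, 0.322, 0.228, 0.238 and 0.259, limma), and leaving out 2 B replicate 1, 2 or 4 ended that of the second higher gene (0.0961, 0.0719 and 0.0606), as did a pseudocount of 0.1 (0.127). With the replicate number as a block, which left out 2 B replicate 4, all 3 calls ended (adjusted p = 0.444, limma), while the log2 changes went from 2.97, 2.86 and -1.54 to 2.99, 2.76 and -1.52. The count of 3 became 73 without the 0 B plant of replicate 3, and 1 without 2 B replicate 1, 2 or 4.

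With 1 B chromosome (4 against 3), 0 of 19478 genes were called by limma, while 533 had an unadjusted p under 0.05 and 105 passed the authors' deposited q-value. The 0 B plants of replicate 1, 2 and 3 had a mean correlation with their own group of 0.913, 0.902 and 0.940. It was 0.941 to 0.968 in the plants with 1 B chromosome and 0.961 to 0.971 in those with 2. The few calls in both B comparisons therefore do not show that the B chromosome had no effect. Without the 0 B plant of replicate 3 there were 27 calls, and without 1 B replicate 2 there were 2. Fold changes with 1 and with 2 B chromosomes correlated at 0.835 across genes, where the shared 0 B plants alone gave 0.735 in simulation, and the covariance was 0.115 beside a simulated 0.104.

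**Figure D4:**
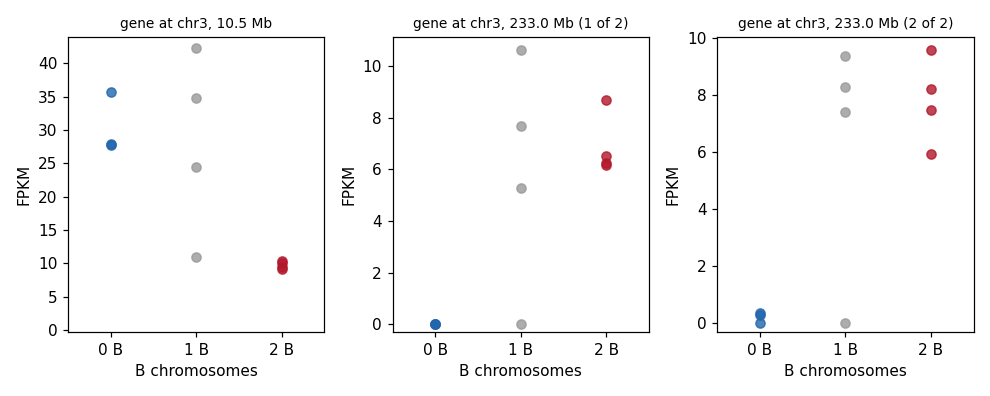
FPKM of the 3 genes called in haploids with 2 B chromosomes, in each plant with 0, 1 or 2 B chromosomes (points). The pair of genes at 233.0 Mb of chromosome 3 was at 5.95 FPKM or more in all 4 plants with 2 B chromosomes and at 0 in 1 of the 4 plants with 1.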

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

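No test of an explanation was run in this part, so no biological or technical explanation was weighed for these samples. In 2 of the 88 sets of values examined, each of them 1 measure in 1 group of at least 4 samples, 1 sample lay far from the others for the range of its set, and chance alone gives this in a share of about 0.05 of sets. The arm score of haploid control replicate 2 in the 2Sa comparison was -0.44, where the other controls lay from -0.48 to -0.47. In 9Sd disomic replicate 3, 20152 genes had an FPKM of at least 1, where the other disomic plants had 19553 to 19592.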

How the results depend on the processing

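The fits of same-numbered samples without a block and the count of genes called in all 7 control sets without the 5Sc set were chosen after the data were seen. The latter gave 83 of 12910 genes measured in those 7 sets (opposite calls in another disomy of a set allowed), beside 92 of 10526 measured in all 8 and called in at least 7. No gene of chromosomes 1 and 2 could enter either count, and none of chromosome 5 the second. The other alternatives were fixed before the data were examined. The count of disomies with more lower than higher trans calls was 13 with a pseudocount of 0.1, without a filter and with the replicate block, 11 by the authors' deposited q-values and 9 after centring. Single disomies changed sides within the 13. Without a filter 7Lb had 3797 higher and 3638 lower and 7Sc 346 and 358, and with the block 2Sa deletion had 362 and 323 and 7Sc 150 and 170. The tip genes were higher in the disomics under every alternative tried except in the 2Sa deletion disomy with a tip of 15 Mb, where the difference was -0.055, since that tip lies outside the run of bins taken as its region. In that disomy the difference was 0.20 with the region from the estimated change point, beside 0.77 for the run of bins. By the authors' deposited q-values the count of calls moved by more than 1.5 times in 2Sa deletion (4028), 4Sa (3359), 7Sc (2541), 8Lc (3366), 9Sd (2800), 1 B (105) and 2 B (433). The 2 B count was 1 with a pseudocount of 0.1 and 5 without a filter, and the cause was not tested. Leaving out 1 sample gave 1443 to 6477 calls in 1Sb, 837 to 1914 in 2Sa deletion, 1173 to 3704 in 3Sb, 1366 to 5439 in 3La, 975 to 1561 in 4Sa, 3096 to 4921 in 5Lb, 2448 to 7942 in 6Lc, 314 to 1210 in 7Sc, 1044 to 1884 in 9Sd, 0 to 27 in 1 B and 1 to 73 in 2 B. The arm difference then ranged from 0.76 to 0.77 in 2Sa deletion, 0.89 to 0.93 in 4Sa and 0.87 to 0.92 in 7Sc, and missed the threshold because the smaller designs cannot give a lower exact p. With the replicate number as a block, calls fell to 953 in 1Sb, 962 in 2Sa deletion, 920 in 3Sb, 734 in 4Sa, 379 in 7Sc and 0 in 2 B, but the block also left out samples without a partner. The same samples without a block gave 2539 in 1Sb, 1886 in 2Sa deletion, 3124 in 3Sb, 1205 in 4Sa, 1095 in 7Sc and 1 in 2 B. In the 4Lb comparison, whose numbers were treated as pairing the samples, the block gave 9638 calls and its samples without a block 9971. Over the other comparisons the correlations of same-numbered samples were as low as -0.408 and as high as 0.507, and in 28 of all 69 same-numbered pairs, those of 4Lb and of the B chromosome comparisons included, the disomic or B sample correlated best with its own number. The block left the arm differences at 0.80 (1Sb), 0.84 (1La), 0.92 (2Sa), 0.77 (2Sa deletion), 0.76 (3Sb), 0.89 (4Sa), 0.91 (4Lb), 0.88 (5Sc), 0.86 (5Lb), 0.89 (7Sc), 0.86 (7Lb), 0.78 (8Lc) and 0.77 (9Sd), with an exact p of 0.0625 or 0.125, the smallest that 4 or 3 pairs allow. The fallen gene of the 2 B comparison had an adjusted p (limma) of 0.0548 with a pseudocount of 0.1, 0.0557 after centring and 0.444 with the block, which ended all 3 calls. The alternatives for gene lists were not run, since the lists were void. Depth could be estimated only roughly, and no counting error can be given for single FPKM values.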

Other observations

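All tests of explanations and all counts over other splits in this part were chosen after the results were seen. Plastid genes, which encode parts of the photosynthetic machinery and of the plastid's own gene expression, differed widely in the authors' deposited poly(A) tables. They were higher in 35 of 77 genes in 3Sb and in 47 of 76 in 6Lc, with none lower, and lower in 29 of 76 in 7Lb and in 61 of 77 in 9Lc, with none higher. In 1La 4 were higher and 6 lower of 78, and in 4Sa 2 and 7 of 78. Genes of the NADH dehydrogenase-like complex were higher in 10 of 10 in both 3Sb and 6Lc, and lower in 9 of 10 in 7Lb and 10 of 10 in 9Lc. In the authors' deposited table rbcL, the large subunit of Rubisco, went from 556 FPKM in the haploids to 110 in 7Lb and 74.5 in 9Lc, and from 83.5 to 226 in 3Sb, while it went from 103 to 189 in 4Sa and from 83.5 to 91.8 in 6Lc (the authors' q = 0.632). For psbA, a subunit of photosystem II, the haploids and disomics were at 92.8 and 95.9 in 3Sb, 92.8 and 174 in 6Lc, 123 and 145 in 7Lb and 123 and 95 in 9Lc, and it fell from 207 to 118 in 1La and from 367 to 225 in 4Sa, which had other haploid sets. The atpB gene, a subunit of the ATP synthase, went from 22.8 to 5.72 in 7Lb and 2.39 in 9Lc, and from 1.64 to 5.61 in 3Sb and 9.91 in 6Lc. The counts of plastid genes called in the poly(A) tables went 1 way in 3Sb and 6Lc, which shared 1 haploid set, and the other way in 7Lb and 9Lc, which shared another, and transcripts of plastids are for the most part not polyadenylated. In the rRNA-depleted libraries only 2 to 8 plastid genes per comparison were tested. There 1 of 3 was higher in 3Sb, 1 of 2 lower in 6Lc, 1 of 5 lower in 7Lb and 3 of 5 lower in 9Lc, with none the other way.

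The genes called in at least 7 of 8 control sets lay in 54 of 272 windows of 5 Mb. These windows leave out chromosomes 1, 2 and 5, whose genes could not be measured in all 8 sets. On chromosome 6, 7 of them lay from 155 to 160 Mb, where random draws of as many genes gave a median of 3 as the fullest window and 8 at most (permutation p = 5e-04, 10000 draws). On chromosome 3, 6 lay from 155 to 160 Mb. By another measure, 67.4% of these genes had another within 5 Mb, against a median of 55.4% in 200 random draws and 69.6% at most (permutation p = 0.0249). Over all trans windows of 5 Mb, the median gene lay beyond 0.35 on the log2 scale in 34 of 5857, against 14.7 after positions were shuffled, and 11 of the 19 different windows also lay beyond it between haploid sets. From 100 to 105 Mb of chromosome 2 the median was 0.60 in 1La, 0.49 in 5Lb, -0.40 in 3La and -0.78 in 6Lc. Between haploid sets, with no difference in dose, this window differed by up to 0.70.

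The genes called the same way in most control sets are a first pattern. If a response to the extra dose of any arm were the whole cause, the 5Sc haploids should lie among the other haploids, but of 76 genes called the same way in all 7 other sets, and the opposite way in no disomy of these sets, only 9, or 11.8%, had a 5Sc haploid mean within their range, which argues against it. A line difference between the disomic plants and most haploid controls may account for these genes, since the 5Sc haploid mean lay nearer to the disomic mean at 67 of them, or 88.2%. The other control sets did so at 0 to 23.5% of their genes. Their lists held only 13 to 21 genes, each also called against the 5Sc haploids, so this is no like comparison. An earlier form of this test used all 92 genes, of which 65 lay nearer to the disomics in the 5Sc set, 1 to 18 in the other control sets, and 28, 40 and 42 in the haploids with 0, 1 and 2 B chromosomes, and was replaced because the choice of genes favoured the 5Sc set. A dose response in part of the genes stays open.

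The number of trans calls is a second pattern. A difference in depth is argued against as the whole cause, since 5Sc, with a depth ratio of 0.989, the nearest to 1, had 4371 trans calls, above the median of 3739. The next nearest were 3La (ratio 1.03, 3698 calls), 2Sa (1.03, 4867), 7Sc (1.05, 697) and 4Lb (1.07, 7083). An earlier form of this test looked at the 3 disomies with the largest depth ratios, which had 1330, 1215 and 1366 trans calls. Plants of different sets grown or prepared apart could account for many calls, because 2 haploid sets differed by a median of 5835 calls, or 29.2% of genes on all chromosomes, with no difference in dose, and the labels do not say which plants were grown together. Over trans genes, only 8 of the 17 disomies lay nearest to their own control set. The 5Sc haploids carry plant names of the same form as the 5Sc disomics, unlike the other control sets. The effect of the extra arm, which the design names, also stays open.

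The preponderance of lower calls is the last pattern. In 5 of the 13 disomies with more lower calls, the median trans shift differed by more than 2 SE from that given by the varied chromosome's FPKM gain. The shift was lower than that in 1Sb (-0.24 ± 0.071, SE, beside -0.048) and 1La (-0.13 ± 0.040 beside -0.043). It was also lower in 4Lb (-0.11 ± 0.018 beside -0.019) and 5Sc (-0.11 ± 0.017 beside -0.052). This argues against the gain as the whole cause in these disomies. In 9Lc the gain gives more lowering than was seen (-0.0040 ± 0.022 beside -0.058). The rest of the 13 lay within 2 SE, so the gain stays open there. A few genes taking most of the FPKM are argued against as a cause common to the 13, since only 8 had a higher share in the top 100 genes. In 3 of them (3Sb, 5Sc and 6Lc) the share was lower by more than 2 SE. Outside these 3 this cause stays open. The share was higher by 8.06 ± 2.49 percentage points (SE) in 1Sb, which had the lowest median trans gene. It was higher by 2.15 ± 0.79 in 2Sa, 2.25 ± 0.73 in 3La and 2.79 ± 0.91 in 10L19. The authors' scaling cannot be told apart from a true shift, because centring, after which 9 disomies, 9Sd among them, had more lower calls, removes a shift of any origin. A difference in depth was not tested for the direction of the calls, so it stays open. The test on the varied chromosome was first made with a tolerance of 0.03, which 7 of 17 disomies met, and then with 2 SE over all 17, which 7 exceeded, before it was limited to the 13.

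Other splits of the same samples into groups of the same sizes were counted, up to 100 per comparison. A share of splits under 0.05 was taken to argue against chance for the calls over all genes, with no adjustment over the 19 comparisons. In the disomies these counts include the varied chromosome, whose dose itself parts disomics from controls. In 8Lc 382 tip genes alone were called higher, beside a highest other count of 1. The splits therefore cannot decide whether the trans calls arose by chance. In 16 of the 19 only the real split gave as many calls. Among the disomies this was so in 1 of 35 splits for 1La (real 6257, highest other 1), 2Sa (5944 and 1), 2Sa deletion (2282 and 25), 4Sa (1781 and 9), 5Sc (5501 and 2), 5Lb (4653 and 2), 7Sc (915 and 195), 8Lc (2223 and 1) and 9Sd (1685 and 1), and in 1 of 100 for 7Lb (8206 and 1224), 9Lc (8941 and 1) and 10L19 (11045 and 1). In 4Lb this was so in 1 of 56 (8192 and 35), but its numbers were treated as pairs, and the 7 other splits that parted all 3 pairs, with at most 1 call, are too few for a share under 0.05. In 1Sb 2 of 100 splits gave as many (real 3420, highest other 3426, with disomic replicates 2 and 3 among the controls), and in 3Sb 2 of 56 did (3126 and 3269, with disomic replicates 3 and 4 among the controls). Both shares lie under 0.05, but a grouping that mixed disomics with controls gave more calls than the real one. The calls of 1Sb and 3Sb therefore cannot be credited to the real grouping alone. What else differs among these samples was not tested. The splits were too few for a share under 0.05 in 3La, with 1 of 10 (4765 and 1), and in 6Lc, with 1 of 10 (5345 and 0). For 2 B the real split alone, 1 of 35, gave 3 calls beside a highest other of 1, but this is a gap of only 2 genes, and without 2 B replicate 1, 2 or 4 the count was 1. For 1 B all 35 of 35 splits reached the real count of 0, as every split must, so this decides nothing about chance. The highest other, 2720, parted 0 B replicate 2 and 1 B replicates 1, 2 and 4 from the rest. It was picked as the highest of the 35, and what sets these samples apart was not tested.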
